A study of Homo sapiens with 20 samples.

How the data were processed

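Bulk mRNA expression was measured in 20 libraries: HT1376 with an empty pLKO.1 vector, with sh4 or with sh5, and T24 with a Myc-tag vector or Myc-tagged TRAF4, with 4 replicates per group. Per the labels' protocols, cells were grown in DMEM with serum, transduced HT1376 cells were selected in puromycin, poly(A) RNA was taken from total RNA, and random-primed libraries were sequenced on a BGISEQ-500 or DNBSEQ instrument. The labels call the replicates independent experiments and the groups derivative cell lines. Whether each replicate had its own transduction is not given in the sources used here, so p-values measure the spread between these cultures and not between transduced populations. Each hairpin and each vector was therefore compared as 1 derivative line.

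The authors deposited 1 table of whole-number counts per Ensembl gene, not normalized, with the count of reads that named no gene. Per the submitters' processing notes the tools were cutadapt 2.8, STAR 2.7.3a and HTSeq 0.11.2 with the GRCh38 genome. Their roles, the annotation release and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes are uncertain. Reads that could come from near-identical genes (the HLA class I genes, KRT6 genes, the keratins 14, 16 and 17, SAA1 and SAA2) may be split or lost. The reads that named no gene made 17.5% to 19.4% of the table per library, of which ambiguous reads were 9.92% to 10.7% and reads in no feature 2.66% to 4.74%. They were left out of library sizes and tests. PCR duplicates were not marked by molecular identifiers, so floors and intervals cover counting error only.

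Of 60676 gene IDs, 42101 (69.4%) were given a symbol from a table of gene names, 92 of these from GENCODE 29, and positions were taken from GENCODE 29 (GRCh38). Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1; DESeq2 1.42.0 was an alternative. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for sequence searches and plots. Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), libraries were scaled by TMM factors, and groups were compared with edgeR's robust quasi-likelihood fit and test. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The 12 HT1376 libraries were fitted together and the 8 T24 libraries apart, while the control lines were compared in a fit of all 20. CPM values are TMM-scaled. Single values were compared by a two-sided exact permutation test over 70 arrangements.

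Before the data were examined, 21 gene lists with 378 members, the tests, the rule for named genes and the alternatives were fixed. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with at least 3 members tested. Of 51 list tests past the threshold, 38 lost the call with an estimated correlation, and each such p is given beside its list. No list past the threshold had a median, mean and test of different sign, while 16 of the 53 others did. The named genes were TRAF4, the 10 up and 10 down with the largest smaller change in both hairpins, the 10 up and 10 down in T24, and the 4 up and 4 down between hairpins and between lines. These needed a mean log2 CPM of at least 3 and groups that did not overlap. The 5 genes most opposite between knockdown and over-expression, up to 4 members of each list with the smallest p, and ID1, ID2, ID3, SMAD6, SMAD7, SMURF1, NFKBIA, CDH1, VIM and CDH2 were also named. Values of some genes named under 1 hairpin are also given for the other hairpin, a choice made after they were seen. VIM and CDH2 were close to 0 in HT1376, so their changes are given for T24 and the lines only. Of the list members that this rule selects, the text gives examples and not every one, chosen after their values were seen, and the result of 1 gene is not reported here. A fold against a group at 0 was computed against a floor of 3 counts over the group.

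The pipeline was tested on simulated counts with 200 changed genes, drawn from the better-expressed ones, and the cholesterol synthesis list raised 1.5-fold. Recovery of low-count genes, and of as many changes as the hairpin comparisons called, was not tested. For sh4, 98% of genes changed 1.5-fold and all changed 2-fold or more were recovered among 15438 genes, with 7 false calls among 210. For over-expression the same shares were recovered among 13928 genes, with 20 false calls among 227, a share above the adjusted p threshold. Of genes changed 1.25-fold, 72% were recovered for sh4 and 82% for over-expression. In each simulation 2 lists passed although only the cholesterol list was raised, so a list that was not raised passed too. Every pair of replicates differed by more than sampling noise in a chi-square test of counts, so none was counted as 1 library. Libraries that share a replicate letter were checked for pairing by the correlation of their deviations from the group means. Between sh5 and sh4 every letter had r above 0.1 (0.117 to 0.499), the rule used here for pairing. The correlation was highest with the own letter for only 2 of 4 letters, so whether the letters pair these libraries is not settled. The fit with the letter as a block called 8385 genes against 8259. Other groups did not meet the rule.

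Alternatives were DESeq2 size factors, no low-count filter, the DESeq2 Wald test, limma-voom, a test against a fold of 1.5, the replicate letter as a block, other sets of libraries in the fit, each library left out in turn, and, for lists, an estimated correlation or fry. Library sizes alone, and 3 further gene lists (antigen presentation, acute phase and complement, keratinocyte differentiation), were added after seeing the data. Overlaps between the hairpins were set beside simulations of unchanged groups and beside splits of the controls.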

Results

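Poly(A) RNA was sequenced from 20 libraries of HT1376 and T24, established human bladder cancer cell lines, in 5 groups of 4 replicates. HT1376 cells had been transduced with lentivirus carrying an empty vector or 1 of 2 short hairpin RNAs against TRAF4, here called sh4 and sh5. T24 cells stably over-expressed Myc-tagged TRAF4 or carried the Myc-tag vector. TRAF4 encodes an adaptor protein of the TNF receptor-associated factor family, and the series asked how mRNA levels change when its level is lowered or raised. The libraries held between 17843577 and 20297456 counts assigned to genes, so depth differed little between groups. Between 22681 and 27366 genes had at least 1 count in a library. The sh4 libraries detected 27150.8 ± 165 genes (SD, n = 4), against 25243 ± 138 in the empty-vector libraries and 25580.2 ± 271 with sh5.

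TRAF4 (ENSG00000076604, protein coding, GRCh38 chromosome 17, 28743984 to 28750958, plus strand) was measured first, as a check of the labels. Its level was 94.0 ± 3.07 CPM (counts scaled per-million; SD, n = 4) in HT1376 with the empty vector, 23.0 ± 2.75 with sh4 and 28.4 ± 1.53 with sh5. It was 4.09-fold lower with sh4 (log2 fold change -2.03, SE 0.0634) and 3.31-fold lower with sh5 (log2 fold change -1.73, SE 0.0623). The sh5 libraries kept 1.23-fold more TRAF4 than the sh4 libraries (log2 difference 0.30, SE 0.0681, edgeR adjusted p = 0.000507). In T24 the gene rose from 41.5 ± 1.51 to 385 ± 17.8 CPM (SD, n = 4), a 9.28-fold increase (log2 3.21, SE 0.0378). The raw counts were 1745 to 1871 in the HT1376 control, 406 to 543 with sh4, 513 to 604 with sh5, 775 to 861 in the T24 control and 6662 to 8238 with over-expression. Groups did not overlap in any of the 4 comparisons, and the two-sided exact permutation p was 0.0286 in each, the smallest that 4 against 4 libraries can give. By TRAF4 level, all 20 libraries matched their labels as control, knockdown or over-expression. That level hardly parts the hairpins (26.2 CPM in sh4 replicate D and 26.8 in sh5 replicate A), so it cannot tell which one a library carries.

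**Figure D1:**
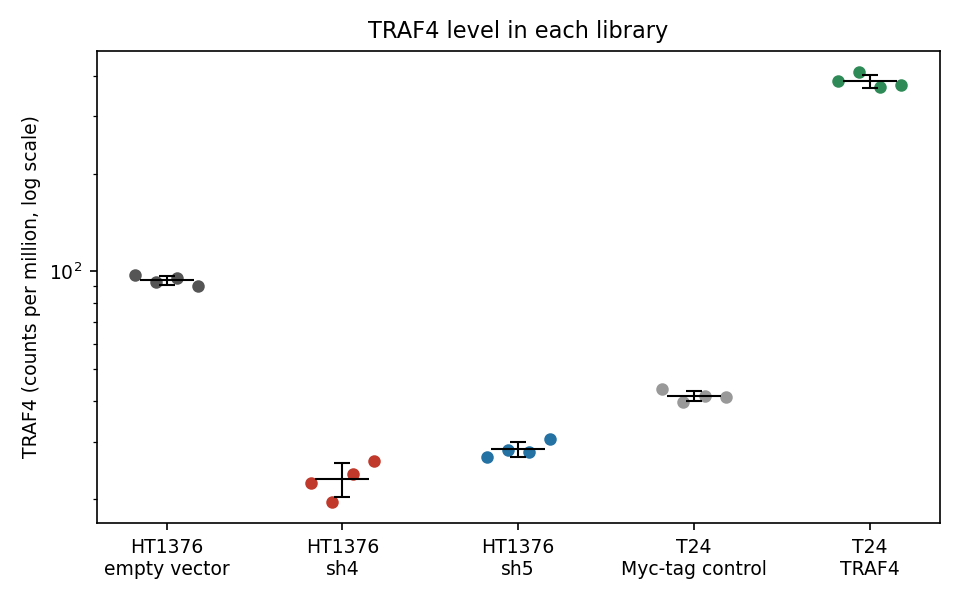
TRAF4 in each library, in CPM on a log axis; points are libraries, horizontal marks group means and bars 1 SD (n = 4). The sh4 and sh5 means are 23.0 and 28.4 against 94.0 in the HT1376 control, and the T24 means are 385 and 41.5.

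The first comparison asked which genes both hairpins move relative to the empty vector. Genes ranked by size here, and in the difference between the hairpins, had a mean log2 CPM of at least 3 over the 12 HT1376 libraries and groups that did not overlap. TRIM22, an antiviral ubiquitin ligase, was 7.59-fold higher with sh4 (log2 2.92, SE 0.282) and 4.13-fold higher with sh5 (log2 2.05, SE 0.296; n = 4 per group). GBP4 and GBP1, interferon-inducible guanylate-binding proteins, rose 7.41-fold and 2.68-fold with sh4 and 3.86-fold and 2.64-fold with sh5. The other genes with the largest rise in both were STEAP4, a metalloreductase (5.40-fold and 4.05-fold), TRANK1 (4.24-fold and 2.85-fold), ADAMTS1, a secreted metalloprotease (log2 1.43 and 1.41), TFPI2, a protease inhibitor (6.03-fold and 2.57-fold), and NMU, a neuropeptide (19.6-fold and 2.56-fold). HCP5 (5.76-fold and 2.88-fold), a noncoding gene within the HLA region, and IGFL2-AS1 (3.44-fold and 4.09-fold), an antisense gene, completed these 10, and both are uncertain because the strand setting of the counting is not given. Genes that fell most in both included IGFBP2 and IGFBP1, which bind insulin-like growth factors, at log2 -1.75 and -2.12 with sh4 and -1.96 and -1.20 with sh5. DBN1, an actin-binding protein (-1.57 and -2.13), LY6E, a GPI-anchored surface protein (-1.47 and -3.25), TGM2, a transglutaminase (-1.79 and -1.28), and HPCAL1, a calcium sensor (-1.13 and -1.62), fell as well. KIAA1549L (-1.34 and -1.27), MARCHF4, a membrane-bound ubiquitin ligase (-1.29 and -1.15), and the noncoding BCYRN1 (-1.80 and -1.56), which is repeat-derived and uncertain, were the others. Every library of both hairpins lay beyond every control library for each of these genes.

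Of 16128 genes tested, 3550 passed the threshold in the same direction with both hairpins, 1647 up and 1903 down. The numbers expected from independent lists were 890.0 and 941. A further 1109 genes passed it in opposite directions, which is 23.8% of the 4659 called with both hairpins. Of these, 559 rose with sh4 and fell with sh5 and 550 did the reverse, where independent lists give 942 and 889. Both comparisons share the same control libraries. In 40 simulations every group, controls included, was drawn from the control means, and at most 1 gene was called in the same direction by both. Such draws hold no difference between derivative lines. With 2 of the real controls used for each hairpin, 6 such splits gave 2336 to 2437 genes and correlations of 0.190 to 0.239. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had Pearson r = 0.266 and Spearman rho = 0.347. Their covariance was 0.0944 against a simulated covariance of 0.0129, and the simulated correlation was 0.509.

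**Figure D2:**
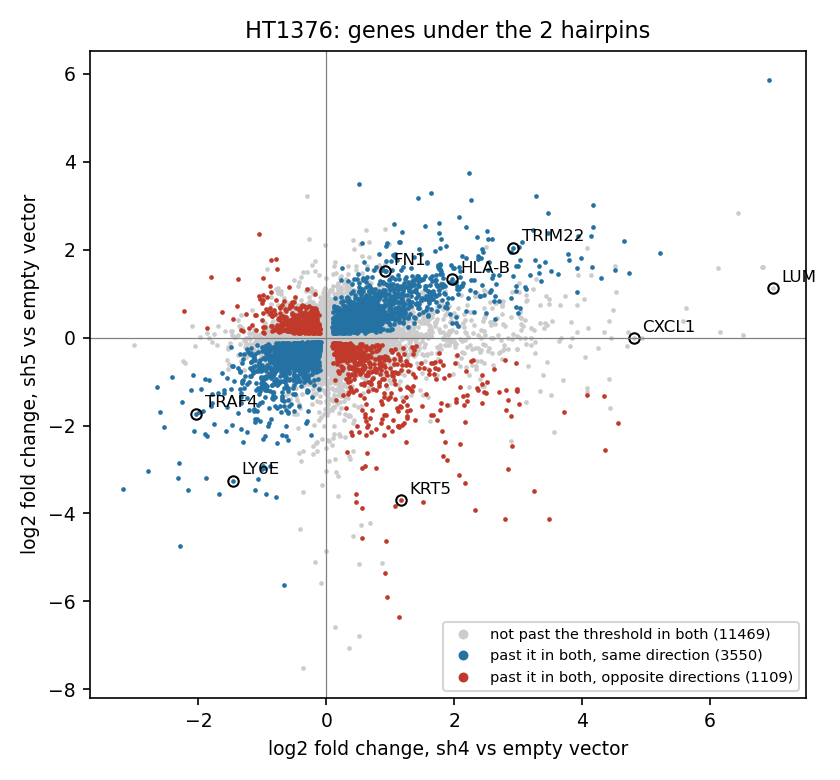
Log2 fold change against the empty vector with sh4 (horizontal axis) and sh5 (vertical axis) for each of the 16128 genes tested; blue points passed the threshold with both hairpins in the same direction (3550 genes), red points in opposite directions (1109 genes) and grey points did not pass it in both. LUM and CXCL1 lie far to the right, near 0 for sh5 in the case of CXCL1, and KRT5 rose with sh4 and fell with sh5.

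With sh4 the largest rise among the genes named here was that of LUM, the collagen-binding proteoglycan lumican, from 0.919 ± 0.163 to 118 ± 16.9 CPM (SD, n = 4; log2 6.99, SE 0.269). DCN, the related proteoglycan decorin, rose from 0.209 ± 0.126 to 19.8 ± 4.47 CPM, and COL3A1, a fibrillar collagen, 4.32-fold to 112 ± 9.55 CPM. Of 20 measured NF-kappaB target genes 19 rose, none fell and 1 did not pass the test, with the same counts adjusted over the list alone (median log2 1.30, camera adjusted p = 1.2e-23, and adjusted p = 0.00218 with an estimated correlation). The chemokines CXCL1 and CXCL8 rose 28.1-fold and 9.19-fold and CXCL10 by 4.70 on the log2 scale, RELB, an NF-kappaB subunit, 4.35-fold, and NFKBIA, the inhibitor of NF-kappaB, 1.75-fold. Of 22 interferon-stimulated genes 21 rose and 1 fell, also adjusted over the list alone (median 1.60). RSAD2 (5.93-fold), OASL (4.10-fold), USP18 (3.04-fold) and the RNA sensor IFIH1 (2.74-fold) were examples, and the list gave adjusted p = 0.195 with an estimated correlation. Mesenchymal genes rose in 11 of 17, with 1 lower and 5 not called, also adjusted over the list alone (median 0.52, adjusted p = 0.0227 with an estimated correlation). Among them were COL1A1 (2.40-fold), COL1A2 (2.08-fold), the integrin ITGA5 (2.09-fold) and fibronectin, FN1 (1.89-fold).

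Other lists passed the preset test with sh4 and lost the call with an estimated correlation, whose adjusted p follows each. Basal and squamous genes rose in 12 of 20 and fell in 5 (0.156): keratin 16, KRT16, rose 2.59-fold and the desmosomal cadherins DSG3 and DSC3 3.70-fold and 1.53-fold, while EGFR fell by 0.39 on the log2 scale. All 7 measured leukocyte, endothelial and fibroblast markers rose (median 1.57, 0.149), and the fibroblast markers LUM, DCN and COL3A1 are members of that list. WNT target genes rose in 5 of 9 and fell in 2 (0.195), with APCDD1, a WNT inhibitor, 7.84-fold higher and DKK1 lower at log2 -1.07. YAP-TEAD targets rose in 7 of 14 and fell in 2 (0.287), TGFB2 by 3.10-fold and FSTL1 by 1.92-fold. Invasion proteases and inhibitors rose in 8 of 17 and fell in 3 (0.195), the gelatinase MMP9 by 7.14-fold and the plasminogen activator PLAT by 1.78-fold. The p53 targets rose in 8 of 18, fell in 2 and were not called in 8 (median only 0.07, 0.219). The rises included CDKN1A (2.23-fold), the death receptor FAS (2.65-fold) and BBC3 (2.03-fold). ERK pathway output genes fell in 11 of 20 and rose in 4 (0.298), with ETV5 at log2 -1.03, DUSP6 at -0.65 and DUSP5 at -0.61. Unfolded protein and stress response genes fell in 12 of 20 and rose in 4 (0.298), including the cystine transporter SLC7A11 (-1.18) and the chaperone HSPA5 (-0.35). Mitochondrially encoded genes fell in 11 of 13 (0.444), MT-ATP6 by 0.98 and MT-CO3 by 0.84 on the log2 scale. Their share of the counts was 6.82% ± 0.226 with sh4 and 8.32% ± 0.652 in the control (SD, n = 4). Adjusted over the list alone, these counts were unchanged except for the p53 list (3 down) and the invasion list (9 up).

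The luminal urothelial list (4 up, 7 down, adjusted p = 0.0704) and the epithelial list (11 up, 7 down, 0.773) did not pass the test with sh4, the former passing without control replicate D (0.0441) or sh4 replicate A (0.0412). Cell cycle genes did not pass either (14 of 25 up, 6 down, or 15 up adjusted over the list alone; median 0.14, adjusted p = 0.0557, and 0.298 with an estimated correlation). That list passed without a low-count filter (0.0108), with library sizes alone (0.0120) and without control replicate D (0.0441), sh4 replicate A (0.0412) or sh5 replicate D (0.0483). TGF-beta targets (9 of 16 up, 2 down, adjusted p = 0.0979) passed without a low-count filter (0.0179), and cholesterol synthesis genes (9 of 20 up, 4 down, 0.0979) with library sizes alone (0.0446). Of the luminal and epithelial members, PPARG, a regulator of urothelial differentiation, fell by 1.22, and the keratins KRT8 and KRT18 fell by 0.70 and 0.69 on the log2 scale. CDH1, the epithelial cadherin, rose 1.39-fold. The BMP-SMAD target list did not pass (3 of 11 up, 4 down, or 4 and 5 adjusted over the list alone; adjusted p = 0.591, and 0.769 with an estimated correlation). Its test and median (-0.21) pointed down and its mean (0.12) up, and BAMBI, a BMP pseudoreceptor, rose 6.96-fold from 0.174 ± 0.176 to 1.22 ± 0.291 CPM (SD, n = 4), or by 3.73 on the log2 scale without control replicate C. Among its other members and related genes, ID1 fell by 0.29, ID3 by 0.12 and SMAD7 rose by 0.41 on the log2 scale, while ID2 (-0.32, adjusted p = 0.0588), SMAD6 (0.25, adjusted p = 0.0544) and the ubiquitin ligase SMURF1 (0.08, adjusted p = 0.311) did not pass. In all, 8344 of 16128 genes passed with sh4, 4174 up and 4170 down, and 1014 of the rises and 246 of the falls were at least 2-fold. With library sizes alone in place of scaling factors, an alternative chosen after seeing the data, 65.5% of the calls were up. Among alternatives, the ID3 call was lost without control replicate A, C or D or sh4 replicate A or B (adjusted p from 0.0567 to 0.127), with all 20 libraries in 1 fit (0.290) and with library sizes alone (0.655). ID2 passed with DESeq2 (adjusted p = 0.0460), limma-voom (0.00707), the replicate block (0.0224), all 20 libraries in 1 fit (0.0280) or these 2 groups alone (6.47e-06), and without sh5 replicate B or D (0.00409 and 0.00102). SMAD6 passed with all 20 libraries (0.0459), these 2 groups alone (0.0492) or library sizes alone (0.0106), and without control replicate A, sh4 replicate A or sh5 replicate D (0.0440, 0.0118 and 0.0449). With library sizes alone SMURF1 passed (0.0445). The WNT list was lost with library sizes alone and without sh4 replicate C (adjusted p = 0.0568 and 0.0540).

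With sh5 KRT5, a basal keratin, fell from 110 ± 18.6 to 8.58 ± 4.87 CPM (SD, n = 4; log2 -3.69, SE 0.319), and KRT6A from 104 ± 18.7 to 7.28 ± 1.26 CPM (log2 -3.83, SE 0.232). Of 20 basal and squamous genes 13 fell, 1 rose and 6 were not called, or 15 down and 1 up adjusted over the list alone (median log2 -0.80, camera adjusted p = 8.42e-09, and adjusted p = 0.0083 with an estimated correlation). DSG3 fell by 2.79 and the surface glycoprotein CD44 by 0.36 on the log2 scale, while DSC3 was the member that rose, 1.35-fold. ERK pathway output genes fell in 15 of 20 and rose in 1, also adjusted over the list alone (median -0.53, adjusted p = 0.119 with an estimated correlation). The ETS factors ETV4 and ETV5 fell by 1.33 and 1.22, FOSL1, an AP-1 subunit, by 1.35 and the phosphatase DUSP6 by 0.64 on the log2 scale.

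Among the other lists, interferon-stimulated genes rose in 9 of 22 with none lower, also adjusted over the list alone (median 0.51, adjusted p = 0.756 with an estimated correlation), including IFIT3 (2.26-fold), RSAD2 (2.13-fold), IFIH1 (1.60-fold) and RIGI (1.51-fold). Unfolded protein and stress response genes rose in 12 of 20 and fell in 3, or 14 and 3 adjusted over the list alone (adjusted p = 0.548 with an estimated correlation). ATF3 was 1.86-fold and DNAJB9 1.76-fold higher and HSPA5 rose by 0.32 on the log2 scale. That list was lost without control replicate A or sh5 replicate A (adjusted p = 0.0628 and 0.0524). The p53 targets rose in 8 of 18 with none lower, also adjusted over the list alone (median 0.08, adjusted p = 0.385 with an estimated correlation). BTG2 was 1.61-fold, PMAIP1 1.53-fold and CDKN1A 1.41-fold higher. Cell cycle genes fell in 11 of 25 and rose in 3, or 12 and 5 adjusted over the list alone (median -0.06, adjusted p = 0.385 with an estimated correlation). The replication helicase subunit MCM3 fell by 0.99, CCNE1 by 0.60, the kinase PLK1 by 0.52 and CCNB1 by 0.49 on the log2 scale. NF-kappaB target genes did not pass as a list (5 up, 3 down and 12 not called, median -0.06, adjusted p = 0.602, with the test pointing up). BIRC3, an inhibitor of apoptosis, rose 2.21-fold and NFKBIA 1.19-fold, whereas CXCL1 (log2 -0.02, adjusted p = 0.976), CXCL8 (-0.02, 0.957), CXCL10 (-0.19, 0.658) and RELB (-0.07, 0.730) did not pass. LUM was at 2.03 ± 1.16 CPM with sh5 (adjusted p = 0.107, but 0.0345 without sh5 replicate D, 0.0435 with these 2 groups alone and 0.0163 with DESeq2) and DCN at 0.220 ± 0.098 CPM (adjusted p = 0.947).

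ID1 fell by 0.64 and ID3 by 0.30 on the log2 scale with sh5, and CDH1 rose 1.10-fold. ID2 (-0.34, adjusted p = 0.0576), SMAD6 (-0.22, 0.129), SMAD7 (0.24, 0.0765) and SMURF1 (0.09, 0.281) did not pass. Without sh5 replicate D, ID2 and SMAD7 passed (adjusted p = 7.87e-05 and 0.0420), and ID2 also with DESeq2 (0.0371), limma-voom (0.00448), the replicate block (0.0190) and all 20 libraries in 1 fit (0.0194). The BMP-SMAD target list did not pass (0 of 11 up, 5 down, or 6 down adjusted over the list alone; median -0.30, adjusted p = 0.0952, and 0.548 with an estimated correlation). It passed without sh5 replicate D (0.0157), without a low-count filter (0.00705) and with the block (0.0384). Mitochondrially encoded genes did not pass either (6 of 13 up, 0 down, or 7 up adjusted over the list alone; median 0.21, adjusted p = 0.0952, and 0.782 with an estimated correlation). They passed without sh5 replicate D (0.00255), without control replicate C (0.0120), without a low-count filter (0.00313) and with the block (0.0384). Their share of the counts was 9.67% ± 0.962 with sh5 and 8.32% ± 0.652 in the control (SD, n = 4). In all, 7077 genes passed with sh5, 3439 up and 3638 down, and 386 and 456 of them changed at least 2-fold. Replicate D stood apart from the other sh5 libraries in the comparison of replicates, and without it 7169 genes passed.

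The difference between the hairpins was tested directly, as sh5 minus sh4. KRT4 (log2 -6.27, SE 0.261), KRT6A (-4.90, SE 0.229), KRT5 (-4.85, SE 0.317) and the cytokine IL32 (-4.27, SE 0.167) were the 4 with the largest lower values in sh5 under the rule on mean level and overlap given above, from 4 libraries per group. CAPN6, a calpain-family protein (log2 2.98, SE 0.079), STC1, a secreted glycoprotein (2.62, SE 0.0719), and HPGD, which degrades prostaglandins (2.58, SE 0.144), were the highest in sh5 by the same rule, with PPIAP46, a pseudogene of a multigene family and so uncertain, at 2.84. KRT6C (-6.85), DCN (-6.45), LUM (-5.86) and MMP9 (-5.83) were lower by more than KRT6A but under that mean level. NF-kappaB target genes were lower in sh5 in 18 of 20 with none higher, also adjusted over the list alone (median -1.40, adjusted p = 0.00266 with an estimated correlation). CXCL10 differed by -4.89, CXCL1 by -4.83, CXCL8 by -3.22, RELB by -2.19 and NFKBIA by -0.55. Basal and squamous genes were lower in 16 of 20 and higher in 1 (median -1.64, 0.00266), including DSG3 (-4.68) and KRT16 (-1.65). Mesenchymal genes were lower in 13 of 17 and higher in 2 (median -0.75, 0.0115), including COL1A1 (-2.92) and COL1A2 (-1.18). WNT target genes were lower in 8 of 9, or in all 9 adjusted over the list alone (median -1.56, 0.0361), including RNF43 (-1.93), a ubiquitin ligase that limits WNT receptors.

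Other lists passed the preset test and lost the call with an estimated correlation, whose adjusted p follows each. Interferon-stimulated genes were lower in sh5 in 20 of 22 (0.367), cell cycle genes in 20 of 25 (0.0735), ERK pathway output genes in 13 of 20 with 2 higher (0.484) and YAP-TEAD targets in 8 of 14 with 2 higher (0.279). Invasion proteases were lower in 9 of 17 with 3 higher (0.0946) and the leukocyte, endothelial and fibroblast markers in 5 of 7 (0.130). Stress response genes were higher in 14 of 20 with 1 lower (0.120), as were 12 of 13 mitochondrially encoded genes (0.350). Adjusted over the list alone, 1 more gene was lower in each of the interferon, cell cycle and ERK lists. The ERK list was lost without sh4 replicate D or sh5 replicate B or C (adjusted p from 0.0646 to 0.0726). CDH1 (-0.33) and ID1 (-0.35) were lower in sh5. In all, 8259 genes differed, 4069 higher and 4190 lower in sh5, and 32.9% instead of 49.3% of the calls were higher with library sizes alone.

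**Figure D3:**
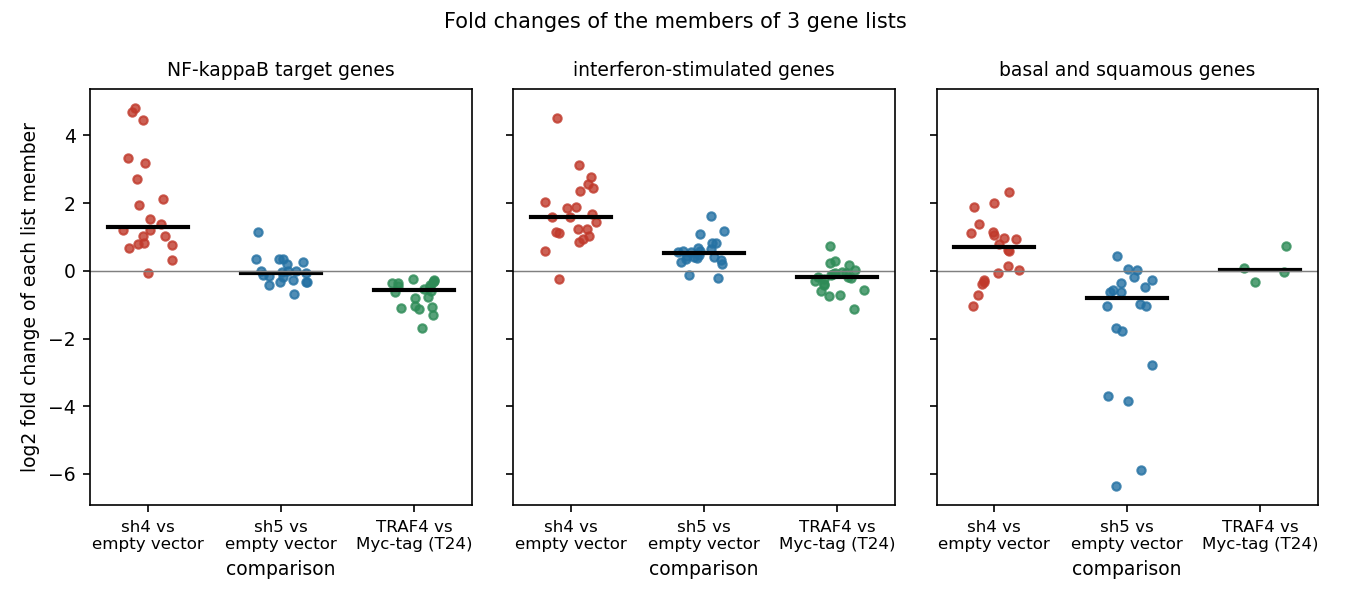
Log2 fold change of each measured member (points) of the NF-kappaB, interferon-stimulated and basal and squamous lists with sh4, sh5 and TRAF4 over-expression, each against its own control; thick lines are medians. The NF-kappaB medians are 1.30 with sh4, -0.06 with sh5 and -0.56 with over-expression, and the basal and squamous list has only 4 members measured in T24.

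NF-kappaB target genes were lower in the T24 line with TRAF4 over-expression than in its control line. Of 20 measured members 18 fell, none rose and 2 did not pass, or 19 fell adjusted over the list alone (median log2 -0.56, camera adjusted p = 9.84e-52, and adjusted p = 0.002 with an estimated correlation). IL1A, the cytokine interleukin 1 alpha, fell from 23.4 ± 1.82 to 9.43 ± 1.57 CPM (SD, n = 4; log2 -1.31, SE 0.0845) and CXCL1 from 395 ± 18.7 to 257 ± 6.98 CPM (log2 -0.62, SE 0.0319). BIRC3 fell by 1.03, RELB by 0.81, TNFAIP3, a negative regulator of the pathway, by 0.76 and NFKBIA by 0.43 on the log2 scale. The other genes with the largest falls, among those with a mean log2 CPM of at least 3 in T24 and no overlap of the groups, were SPNS2, a sphingosine-1-phosphate transporter (-1.49), PXDN, an extracellular matrix peroxidase (-1.38), HLA-B (-1.08), INHBB, an activin subunit (-0.95), TAGLN (-0.80) and TGFB2 (-0.79), an actin-binding protein and a growth factor. Rises were smaller apart from TRAF4 itself: RELN, the extracellular protein reelin, rose 2.07-fold, OASL 1.68-fold, the membrane protease MMP16 1.67-fold, FRMD3 1.56-fold and PTHLH, parathyroid hormone-like hormone, 1.54-fold. ID1 (1.44-fold), the clock gene NPAS2 (1.40-fold), the phospholipase PLCB4 (1.40-fold) and MALL (1.35-fold) completed the 10 largest rises by the same rule, and the NPAS2 call was lost without T24 control replicates A or B or TRAF4 replicate C (adjusted p from 0.0551 to 0.0577).

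Unfolded protein and stress response genes fell in 11 of 20 with none higher, or 11 lower and 1 higher adjusted over the list alone (median -0.19, adjusted p = 0.00458 with an estimated correlation). XBP1 fell by 0.26, HYOU1 by 0.24 and HSPA5 by 0.23 on the log2 scale. The BMP-SMAD target list rose (4 of 11 up, 1 down and 6 not called, or 5 up adjusted over the list alone; camera adjusted p = 0.0291, and adjusted p = 0.0994 with an estimated correlation). ID2 rose by 0.73 and SMAD7 by 0.30, NOG, a BMP antagonist, fell by 0.51, and ID3 (0.39, adjusted p = 0.0870), SMAD6 (0.09, 0.794) and SMURF1 (-0.03, 0.778) did not pass. ID3 passed with DESeq2 (adjusted p = 0.0147), limma-voom (0.000318) and all 20 libraries in 1 fit (0.00894), and without T24 control replicate C (0.00785). The BMP-SMAD list was lost with library sizes alone (0.0642) and without TRAF4 replicate A (0.0763). The other lists that passed the preset test lost the call with an estimated correlation. Interferon-stimulated genes fell in 11 of 22 and rose in 3 (adjusted p = 0.0552), with IFI27 at log2 -0.72, MX1 at -0.75 and OAS3 at -0.29 but OASL higher. Cholesterol synthesis genes fell in 14 of 20 (0.100), STARD4, a sterol transport protein, by 0.23, and TGF-beta targets fell in 9 of 16 and rose in 2 (0.0630), PDGFB by 0.71 and TPM1 by 0.41 on the log2 scale. YAP-TEAD targets fell in 6 of 14 (0.0994), NT5E by 0.50 and AJUBA by 0.30, and invasion proteases in 6 of 14 (0.0552), the urokinase PLAU by 0.59 and its receptor PLAUR by 0.33. Epithelial genes fell in 5 of 11 and rose in 1 (0.0552), the tight junction gene CLDN1 by 0.56 and the desmosomal gene DSP by 0.16. Hypoxia genes fell in 6 of 17 and rose in 1 (0.0552), VEGFA by 0.36 and P4HA1 by 0.32. Adjusted over the list alone, 13 interferon, 16 cholesterol, 10 YAP-TEAD, 7 invasion, 6 epithelial and 8 hypoxia genes fell, and 3, 0, 1, 2, 2 and 1 rose.

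In all, 1904 of 14179 genes passed, 651 up and 1253 down, and 26 and 40 of them changed at least 2-fold. The median absolute log2 fold change of the called genes was 0.20. Up calls made 34.2% of the total, and 60.5% with library sizes alone, a split that depended on the scaling. VIM, the mesenchymal filament vimentin, rose 1.21-fold and CDH2, the neural cadherin, fell by 0.24 on the log2 scale. The 7 other TRAF genes did not pass as a list in any comparison, but did with sh4 without sh4 replicate A (adjusted p = 0.0468) and, in the sh4 and sh5 minus sh4 comparisons, without a low-count filter (0.0312 and 0.0164). Here 15 genes passed a test against a fold of 1.5. When all 20 libraries shared 1 fit, 1069 genes passed, and ID2 (adjusted p = 0.0898), IFI27 (0.0764), MX1 (0.199) and OAS3 (0.206) did not.

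Genes moved in opposite directions by lowering and raising TRAF4 were counted over the 13071 genes tested in both lines. Of these, 220 rose with both hairpins and fell with over-expression, where independent lists give 115, and 85 showed the reverse pattern, where they give 82.5. Changes in the same direction numbered 52 up and 179 down, where independent lists give 60.5 and 157. The 5 genes with the largest opposite changes were SAA1, CTSS, LPAR3, HLA-B and BIRC3. SAA1, an acute phase protein, rose 8.69-fold with sh4 and 2.17-fold with sh5, and fell to 0.169 ± 0.0954 CPM from 1.03 ± 0.181 with over-expression. Its level in T24 was thus low, and DESeq2 gave it no adjusted p there. CTSS, the lysosomal protease cathepsin S, rose 15.1-fold and 2.06-fold and fell by 1.23 on the log2 scale. HLA-B, a class I antigen-presenting molecule, rose 3.92-fold and 2.51-fold and fell by 1.08, and BIRC3 rose 2.29-fold and 2.21-fold and fell by 1.03. LPAR3, a lysophosphatidic acid receptor, went the other way, at log2 -2.16 and -3.47 with the hairpins and 2.40-fold higher with over-expression, but stayed under 2 CPM in every group. SAA1 and HLA-B have near-identical relatives, so reads could be split between them. Across genes, which are not independent replicates, log2 fold changes with over-expression had r = -0.108 (rho = -0.00521) with those of sh4 and r = -0.00729 (rho = 0.0323) with those of sh5. The 305 opposite genes became 197 when all 20 libraries shared 1 fit and 4 in the test against a fold of 1.5.

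The control libraries of the lines were compared to describe the backgrounds, in which line and vector differ together. T24 lacked urothelial and epithelial transcripts that HT1376 expressed at high levels. UPK1B, a uroplakin, had 0 counts over the T24 control libraries and 103885 over those of HT1376, a mean of 1351 CPM, which is at least 35189.8-fold lower in T24 with a floor of 3 counts over the group. SPRR3, a cornified envelope protein, was likewise at least 18095-fold lower, and TRIM29 was at 0.0515 ± 0.0733 against 744 ± 30.1 CPM. KRT14 had 1 count over the T24 group, a ratio of 61627 with a 95% exact Poisson interval from 11061 to 2434150, which covers counting error only. CDH1 was at 0.128 ± 0.0507 CPM in T24 and 266 ± 10.1 in HT1376. Higher in T24 were the collagens COL4A2 (569 ± 25.6 against 0.0533 ± 0.0762 CPM) and COL6A2 (548 ± 24.2 against 0.0520 ± 0.00127), the claudin CLDN11 (log2 10.76) and the actin crosslinker FLNC (10.05). VIM (10.24), CDH2 (11.89), ZEB1, a repressor of epithelial genes (9.94), and the receptor kinase AXL (9.01) were also higher. The HT1376 levels of VIM, CDH2, COL4A2 and COL6A2 were close to 0, so their ratios rest on few counts there. COL6A2 was at about 1 count per HT1376 library, so its small SD there reflects library sizes.

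Epithelial genes were lower in T24 in 21 of 22 (median -7.10, adjusted p = 0.000309 with an estimated correlation), with ESRP1 at -9.98 and CLDN7 at -11.15. Basal and squamous genes were lower in 19 of 20 (median -10.35, or -9.83 with the 8 members at 0 in 1 group placed at their bound, 0.000273), including EGFR (-1.28). Luminal urothelial genes were lower in 12 of 13 (median -5.81, 0.00248), with UPK3B at -9.28 and ERBB3 at -6.44. FOXA1, a transcription factor of luminal cells, was the member that was higher in T24, at 55.7 ± 2.93 against 0.0128 ± 0.0256 CPM (SD, n = 4). It had 1 count over the HT1376 group, a ratio of 4286 with a 95% exact Poisson interval from 769 to 169307. Mesenchymal genes were higher in 13 of 21 and lower in 7 (median 1.77, 0.000148). The medians of the epithelial, luminal and mesenchymal lists were unchanged with such genes at their bound. NF-kappaB targets were higher in 14 of 21 and lower in 5 (adjusted p = 0.230 with an estimated correlation), with CXCL8 (7.28) and IL1B (4.24) higher and NFKBIA (-0.88) lower. Also lost with an estimated correlation were the calls for BMP and TGF-beta receptors, SMADs and SMURFs (12 of 19 higher, 5 lower, 0.164), TGF-beta targets (12 of 16 higher, 4 lower, 0.114), cell cycle genes (18 of 25 higher, 5 lower, 0.222) and YAP-TEAD targets (10 of 14 higher, 3 lower, 0.230). The same held for p53 targets (12 of 18 lower, 5 higher, 0.230) and mitochondrially encoded genes (12 of 13 lower, 0.746). Leaving out sh4 replicate A, C or D, which enter the shared fit, ended both of these calls (adjusted p from 0.0504 to 0.0514), and leaving out T24 control replicate C or D that for p53 (0.0544 and 0.0535). Adjusted over the list alone, the counts of all these lists were the same. The BMP-SMAD target list did not differ between the lines by the test (5 of 13 higher, 8 lower, the same adjusted over the list alone; adjusted p = 0.160, and 0.444 with an estimated correlation). ID1 (-1.35), ID2 (-4.49), ID3 (-1.99), SMAD6 (-1.46), SMURF1 (-0.46) and TRAF4 (-1.15) were lower in T24, and MSX1, a homeobox gene (6.01), and SMAD7 (0.45) were higher. In all, 14732 of 17332 genes passed, 6881 higher and 7851 lower in T24, around a median log2 fold change of -0.09 over all genes (-0.11 with library sizes alone).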

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

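Of the tests in this part, those of the TRAF4-level difference, of NF-kappaB genes following TRAF4 and of the low-baseline fibroblast transcripts were chosen only after the result was seen.

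In 12 lists the hairpins differed from each other in a direct test, as median log2 difference of sh5 minus sh4: NF-kappaB targets -1.40, basal and squamous -1.64, WNT targets -1.56, leukocyte, endothelial and fibroblast markers -1.23, interferon-stimulated -1.04 and mesenchymal -0.75. The others were YAP-TEAD targets -0.46, ERK output -0.41, invasion proteases -0.39, cell cycle -0.25, stress response 0.47 and mitochondrially encoded genes 0.59. With an estimated correlation the NF-kappaB, basal, mesenchymal and WNT lists remained past the threshold.

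The first pattern is that the hairpins lowered TRAF4 mRNA to similar levels and moved these lists apart. A steady response to the TRAF4 level would move genes the same way with both hairpins, yet 23.8% of those called with both went opposite. That share covers all genes and comes from the same fold changes as the pattern, so it is no test of these lists. The pattern could still follow from a threshold, or from a response that changes direction with the TRAF4 level, which was not tested. No NF-kappaB or interferon member lay in 1 of the 33 shifted windows of 50 genes (100% of the median kept). Copy number shifts of the members' own regions therefore did not account for those lists. The 11 of 20 basal members outside the windows kept 119%. The other basal members lay inside, and their own lower values in sh5 may have shifted these windows. Whether the windows reflect copy number thus cannot be told, and it stays open for those members. Other effects of these regions were not tested. Repression through a hairpin seed stays open: the 3 prime UTR heptamer ACTGTGA, also the match of miR-27, had a robust z of -10.48 with sh4 and -0.496 with sh5, while GAAAGCG reached -5.98 with sh5, just short of the limit set beforehand, and 0.53 with sh4. The NF-kappaB, interferon and basal medians kept 99.7%, 91.1% and 101% without members that hold ACTGTGA or TACTGTG. These lists rose with sh4, so repression of members through such sites would have made the difference smaller. The kept shares are therefore no support for an effect through regulators, which was not tested.

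A second pattern is the rise of lumican and other fibroblast genes with sh4. Depth differed by 1.47% between the sh4 and control libraries, too little to account for it. COL1A1, COL1A2, COL3A1 and SPARC together gained 285 ± 43.9 CPM, more than LUM at 114 ± 16.9 (CPM for this pattern were scaled over all 20 libraries, not the 12 of HT1376, so that LUM is at 115 with sh4), which met the criterion set for fibroblasts in the cultures. That criterion was a poor one, since COL1A2 was already at 176 CPM in the control, and 8 fibroblast transcripts, those of a set of 9 that were under 10 CPM there, gained only 3.56 ± 1.94 CPM, with VIM at 0.0235 CPM with sh4; the ninth, FBN1, was at 118 CPM there and gained 70.7. A change within the sh4 cells therefore remains as a hypothesis, with a seed effect (-10.48) and clonal drift of the transduced population among its possible sources, the latter untested.

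The third pattern is that NF-kappaB targets rose with sh4 and fell with over-expression. GC content and gene length did not account for it, as removing their trend left at least 100% of the median (100.2% in T24). A simple dependence on the TRAF4 mRNA level was also not borne out. The list was lower in sh5 than in sh4 by a median log2 of -1.40 although TRAF4 mRNA was low in both. The sh4 libraries enter both this difference and the pattern, and TRAF4 protein was not measured here. A threshold between the sh4 and sh5 levels was not tested. A role of TRAF4 in T24 alone, a seed effect in sh4, or drift between the derivative lines may each remain, the last untested.

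Values that stood apart from the other 3 libraries of their group numbered 23 of 406 groups tested, where chance gives 20.3, with 4 each in sh4 replicate D and HT1376 control replicate C. They were the depth of TRAF4 replicate C (17843577 counts) and the genes detected in HT1376 control C (25037). In CPM they were NMU 86.8 and CAPN6 10.5 in sh4 A, MT-CO3 2929 in sh4 B, and IGFBP2 15.2, OASL 9.98, DUSP6 50.1 and DKK1 2.27 in sh4 D. With sh5 they were HPCAL1 29.4 in replicate B and TGM2 75.3 and MARCHF4 49.6 in D. In the HT1376 control they were LUM 0.677 and VIM 0.103 in A, FN1 191, COL6A2 0.0539 and BAMBI 0.435 in C, and FOXA1 0.0512 in D. In T24 they were SMURF1 53.3, KRT14 0.0510 and CDH1 0.204 in control A, MX1 11.3 in control C and SMAD7 17.0 in TRAF4 C. FOXA1 and KRT14 had 1 count over their groups. COL6A2 was at 0.0512 to 0.0515 CPM in the other HT1376 control libraries, the level of 1 count, so only library size set it apart. VIM was as close to 0, so the values of these 4 genes do not mark a library.

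Reads in no feature, which no comparison used, made 4.36% ± 0.257 of the sh4 libraries and 3.90% ± 0.170 of the control libraries (SD, n = 4, two-sided exact permutation p = 0.0286). They made 4.33% ± 0.285 with sh5 (exact permutation p = 0.0571) and 3.07% ± 0.108 against 2.87% ± 0.150 with over-expression (exact permutation p = 0.0571). No comparison passed after adjustment (0.0571 in each of the 3). The sh4 and control libraries did not overlap (lowest 4.17%, highest 4.14%). The sh4 permutation p of 0.0286 is the smallest that 4 against 4 libraries can give, and alone it cannot pass over 3 tests.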

How the results depend on the processing

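Library sizes alone was the only alternative here chosen after the result was seen. No result reversed. Against a fold of 1.5, 1377 genes passed with sh4, 760 with sh5, 1590 between the hairpins, 15 with over-expression, 9528 between the lines, 228 with both hairpins and 4 in opposite directions, and the TRAF4 difference between hairpins (log2 0.30) did not pass; a stricter null gives fewer calls by construction. With all 20 libraries in 1 fit, 1069 genes passed with over-expression and 197 were opposite; the cause was not tested. With an estimated correlation 2, 1, 4, 2 and 4 lists passed for sh4, sh5, their difference, over-expression and the lines, and with fry, which does not compare a list with other genes, 15 for sh5 and 19 for the lines. Leaving out 1 library at a time gave 7742 to 8859 genes for sh4, 6399 to 7169 for sh5, 7689 to 8407 for their difference, 1440 to 1773 for over-expression, 14668 to 15004 for the lines, 3119 to 3686 for both hairpins and 248 to 328 opposite. TRAF4 then ranged over log2 -2.10 to -1.96, -1.77 to -1.70, 0.23 to 0.37, 3.18 to 3.24 and -1.18 to -1.13 in the same order, and lists past the threshold over 11 to 15, 5 to 8, 11 to 12, 10 in each fit and 9 to 11. With the replicate letter as a block, 8449, 7236, 8385, 1821 and 14741 genes passed, 3660 with both hairpins and 302 opposite. The block moved the BMP-SMAD (adjusted p = 0.0384) and mitochondrial lists past the threshold for sh5, the p53 list of the lines below it (0.0587), and ID2 past it for sh4 and sh5 (0.0224 and 0.0190), and changed no other call of a named gene or list. Outside sh5 minus sh4 the letters gave same-letter correlations from -0.216 to 0.161. Of 231 named gene results, leaving out a library ended 8 calls and added 9 over 2804 fits. Depth limits genes near 0, such as LPAR3, KRT14 and the mesenchymal genes of HT1376.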

Other observations

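The 3 lists below, the histone genes with their neighbours and the test of interferon genes moving with antigen presentation were chosen only after the result was seen; the seed-match test was not. Antigen presentation genes rose with sh4 in 20 of 20 (median log2 1.01, adjusted p = 0.00204 with an estimated correlation) and with sh5 in 19 of 20 (0.84, 0.00914), and fell with over-expression in 16 of 18 (-0.37, 0.00101). They were lower in sh5 than sh4 in 15 of 20 and higher in 3 (-0.38, 0.119), and the lines did not differ by the test (9 higher, 10 lower, 0.957). B2M, the light chain of class I molecules, moved by 1.29, 1.12 and -0.44 on the log2 scale with sh4, sh5 and over-expression, the peptide transporter TAP1 by 1.64, 0.88 and -0.21, and the immunoproteasome subunit PSMB9 by 1.67, 1.07 and -0.42. Acute phase and complement genes rose with sh4 in 11 of 11 (median 3.48, 0.000317), including SERPINA1 (log2 6.16). With sh5 6 rose and 1 fell (0.216), in sh5 minus sh4 10 of 11 were lower (0.000466), with over-expression 3 of 7 fell (0.0102), and the lines did not differ by the test (0.957).

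Keratinocyte differentiation genes rose with sh4 in 11 of 19 and fell in 1 (median log2 0.56, 0.124 as adjusted p with an estimated correlation), and fell with sh5 in 16 of 19 (-2.22, 0.000504), KRT13 by 2.22 and KRT15 by 2.60. In sh5 minus sh4 17 of 19 were lower (-2.92, 0.000466), in T24 against HT1376 all 19 were lower (-9.41, 0.0273), and with over-expression the 3 measured members did not pass (0.989). Of 26 replication-dependent histone genes on chromosome 6, 17 rose with sh5 (median 0.44) and 3 rose and 1 fell with sh4; such transcripts mostly lack a poly(A) tail. All 26 lie between 18120440 and 30486590 of chromosome 6, where windows of 50 genes were shifted with sh5. The 95 other genes there had a median log2 fold change of 0.24, with 39 up and 6 down.

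Interferon-stimulated and antigen presentation genes had the same direction in 3 of 3 comparisons, up with both hairpins and down with over-expression. This is little evidence of a shared program, since the list was chosen on these data, both hairpin comparisons use the same controls, and the interferon list lost its calls with an estimated correlation (adjusted p = 0.195, 0.756 and 0.0552). The interferon list was also lower in sh5 than in sh4 in 20 of 22 members (median -1.04, adjusted p = 0.367 with an estimated correlation) at similar TRAF4 mRNA.

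Whether the sh4 heptamers are the seed match of the hairpin cannot be told apart from a microRNA effect, because hairpin sequences are not given in the sources used here. The octamer TACTGTGA occurs at position 625 of the 2923 bases of the longest TRAF4 transcript, but also in 6.34% of 3469 transcripts of similar length, too many for its presence to decide. For sh5 the octamer TGAAAGCG, joined from heptamers with a robust z of -5.98 and -5.50, had 0 occurrences in that TRAF4 transcript, but GAAAGCG itself occurs in it, as in 8.07% of the transcripts of similar length, so a match of sh5 stays open too. With sh4, 573 genes with TACTGTGA had a median log2 fold change of -0.13 and 45.7% were called down, against 27.2% of genes without these heptamers. The octamer was picked for low values with sh4 in these data, and the shares are not adjusted for UTR length or GC content. This contrast is therefore no separate support for off-target repression, which stays possible.

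Other splits of the same libraries were compared by the number of genes called. Each split into 2 groups but the real one mixes both real groups, so their difference adds to the spread and lowers the calls. The splits show that the libraries part by label, and cannot exclude chance differences between derivative lines. The real split was the 1 of 35 with as many genes for sh4 (8552 genes, highest other 0), sh5 (6812, 1), their difference (7871, 0), over-expression (1904, 14) and the lines (13696, 0), and the 1 of 100 for both hairpins (3550, 0). The sh4, sh5, difference and line counts differ from those in the report because the 2 groups were fitted alone here. Opposite changes numbered 305 in the real split, 1 of 35, and at most 4 in the others, which call at most 14 genes in T24. That count therefore bears on the number of T24 calls and not on direction: 220 genes up with both hairpins fell with over-expression, where independent lists give 115, but 85 went the other way, where they give 82.5. Among the 8 splits that part all 4 letters of sh4 and sh5, the highest other for their difference was also 0.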
